A study of Arabidopsis thaliana with 18 samples.

How the data were processed

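RNA was measured by sequencing in 18 Arabidopsis thaliana Col-0 libraries, 3 for each of 6 groups: leaf discs in 1% mannitol, 1% glucose or 1% fructose, and leaves of wild type and of 2 ERDL4 overexpressor lines. Per the labels, plants grew at 21 °C with 10 h light and 14 h dark, and both discs and leaves came from plants 4 weeks old. The deposited table gives read counts per gene for all 18 libraries, as the authors made them: per the submitters' processing notes, reads were cleaned with fastp (version not given), aligned to TAIR10 with HISAT2 2.0.5 and processed with StringTie 1.3.3. The tool that made the counts and the strand setting are not given in the sources used here. The values were checked to be whole numbers. Of 32833 genes in the table, 32548 matched a locus of the TAIR10.1 reference used here for names and locations, and the other 285, all in the organelle genomes, held 0.0375% of the counts.

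Library totals ranged from 17318810 to 26157641 counts. Each experiment was fitted apart, with 1 mean per group and no replicate block, which left 6 residual degrees of freedom. Genes were filtered with filterByExpr (18784 kept in discs, 18703 in leaves, 17848 in both), scaled with TMM and tested with the robust quasi-likelihood test of edgeR 4.0.16 in R 4.3.3. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Comparisons were fructose and glucose against mannitol, fructose against glucose, each overexpressor and their mean against wild type, and overexpressor 2 against overexpressor 1. Fold changes are log2. Their ± value, called SE here, is the absolute fold change over the square root of its F statistic. It is thus an approximate standard error worked back from the test, whose spread is shared by all groups of the experiment. Levels are CPM, which is TMM-scaled with the standard deviation of 3 libraries. Where a group held 0 counts a bound was taken from a floor of 3 counts over the group, and where it held 1 to 3 counts the ratio is given with its 95% counting interval.

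The groups, tests, named-gene rule, 29 gene lists and most alternative settings were set before the data were examined. The lists held 468 entries (460 distinct loci): vacuolar and plasma membrane sugar transporters, sucrose and hexose metabolism, starch synthesis, starch degradation, trehalose metabolism, sugar starvation, photosynthesis, chlorophyll synthesis, anthocyanin synthesis, nitrogen assimilation, ribosome biogenesis, glucosinolate synthesis, cell wall expansion, the cell cycle, phosphate starvation, the clock, cold, abscisic acid, salicylic acid, jasmonate, low oxygen, heat shock, senescence, and markers of phloem companion cells, guard cells, epidermis, flowers and seed storage. They were tested with camera of limma 3.58.1 at a preset correlation between genes of 0.01, and again with a correlation estimated per list and with fry, with adjustment over 196 tests of 28 lists. Genes named in the text were those of 4 parts of the rule: 11 sugar genes in every comparison, the 5 highest and 5 lowest called genes with a symbol, at least 5 CPM on average and no overlap between the groups' libraries, up to 4 called members of each list with the smallest p and members going against their list, and the 10 genes with the strongest shared change in fructose and both lines. Genes found outside the rule are marked as chosen after their values were seen.

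Pairs of replicates were checked with a chi-square per degree of freedom over genes with a summed count of at least 20. It was 2.06 for replicates 2 and 3 of overexpressor 1, 1.70 for those of overexpressor 2 and 4.60 to 66.3 for the other 16 pairs. All libraries were kept as replicates, and merging near-identical pairs (with mannitol replicates 1 and 2) was added as an alternative after this check, as was leaving out the 100 most abundant genes. The other settings were RLE scaling, library size only, DESeq2 1.42.0, limma-voom, no filter, at least 1 CPM in at least 3 libraries, a replicate block, a fit of the 2 groups alone, all 18 libraries in 1 fit, a log2 fold change of at least 1, an adjusted p under 0.01 and leaving out each library in turn. Overlaps were set against the expectation for independent lists, against 20 simulations of unchanged groups sharing their controls, and tested with Fisher's exact test.

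The pipeline was tested on simulated data with 100 genes changed 2-fold and 100 changed 4-fold. In the fructose comparison edgeR recovered 76% and 92% of these with 4.35% false calls, and in the overexpressor 1 comparison 69% and 94% with 5.59%. DESeq2 gave 15.2% and 16% false calls and limma-voom 2.86% and 5.23%. In limma's camera test a shifted list of 40 simulated genes was called and an unshifted list was not. The simulated genes varied independently of each other, so the preset correlation was not put to the test. Far fewer genes were changed than were called in the real data, so these rates may not carry over. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.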

Results

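The data were RNA-seq read counts per gene from 18 Arabidopsis thaliana Col-0 libraries in 2 experiments on ERDL4, a sugar transporter of the vacuolar membrane, and on the response of leaf tissue to fructose. In the leaf disc experiment, discs cut from plants 4 weeks old were kept overnight in medium with 1% mannitol as an osmotic control, with 1% glucose or with 1% fructose. In the leaf experiment, leaves of wild-type plants were set against leaves of 2 lines that overexpress ERDL4, called overexpressor 1 and overexpressor 2 here. These plants were also 4 weeks old. Each of the 6 groups held 3 libraries. Total counts ranged from 19769388 to 23659648 in mannitol, 19411820 to 21236274 in glucose and 19129210 to 25306880 in fructose. They ranged from 19429580 to 23806098 in wild type, 23268052 to 26157641 in overexpressor 1 and 17318810 to 17519589 in overexpressor 2. The titles call the libraries of a group biological replicates and do not say whether they came from separate plants, so p-values measure only the spread between these samples, which may be technical for the near-identical replicates 2 and 3 of each line.

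ERDL4 (AT1G19450; TAIR10.1 chromosome 1, 6731411 to 6735024, minus strand, 17 exons) was higher in every library of both overexpressor lines than in every wild-type library, as the labels state. The wild-type leaves held 124, 111 and 152 CPM (scaled as described above), overexpressor 1 held 350, 355 and 359 CPM and overexpressor 2 held 604, 578 and 568 CPM. ERDL4 rose by 1.46 ± 0.13 (log2 fold change ± SE, n = 3 per group) in overexpressor 1 and by 2.18 ± 0.13 in overexpressor 2 over wild type (edgeR quasi-likelihood test, adjusted p = 0.000155 and 5.52e-05). In the discs it stood at 47.7, 45.8 and 37.3 CPM in mannitol, 20.3, 23.8 and 27.1 CPM in glucose and 38.3, 37.4 and 33.9 CPM in fructose. ERDL4 fell in glucose against mannitol (-0.88 ± 0.13; edgeR adjusted p = 0.000136). Its change of -0.26 ± 0.13 in fructose against mannitol did not pass the test (edgeR adjusted p = 0.103), and 6 of 20 alternative settings put it past the threshold, with adjusted p from 0.0322 to 0.989 over all of them. ERDL6 is a close copy of ERDL4, so reads that fit both genes may make either level uncertain, which was not tested.

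**Figure D1:**
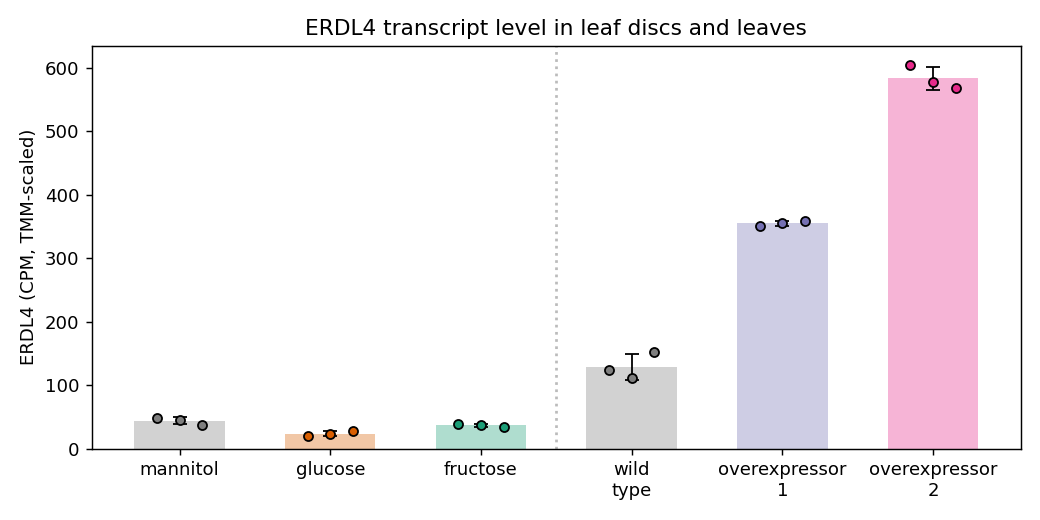
ERDL4 transcript level in CPM for each of the 18 libraries (points), with the group mean (bars from 0) and SD (n = 3 per group). The overexpressor 1 libraries lie between 350 and 359 CPM and those of overexpressor 2 between 568 and 604 CPM, above the wild-type range of 111 to 152 CPM.

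The disc libraries separated by group. The leaf libraries separated wild type from the overexpressor lines, but the lines overlapped on the leading component. In the discs the leading principal component of log2 CPM held 76.2% of the variance and placed mannitol (-142, -142 and -132) opposite glucose (118, 88 and 103), with fructose between them (33.4, 53.6 and 19.8). In leaves the leading component held 71.9% of the variance and placed wild type (-95.9, -63.9 and -101) opposite both lines. The scores were 8.92, 56.4 and 55.9 in overexpressor 1 and 54, 42.7 and 43.3 in overexpressor 2. Wild-type replicate 2 and overexpressor 1 replicate 1 thus lay nearer to the other genotype than the other libraries of their groups.

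**Figure D2:**
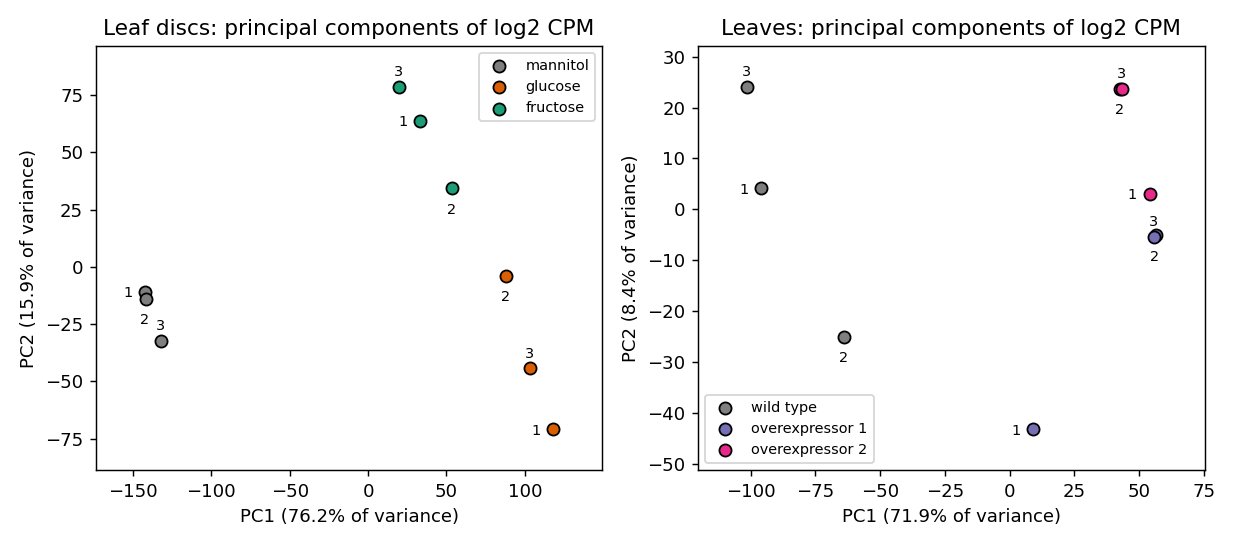
Scores of each library on the leading pair of principal components of log2 CPM, for leaf discs (left) and leaves (right), with colours for groups and digits for replicates. The axes state the share of variance, which is 76.2% for the horizontal axis in discs and 71.9% in leaves.

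The comparison of fructose with mannitol asks which transcripts leaf tissue changes when fructose is supplied. Fructose lowered 20 of 22 genes that leaves use under sugar shortage and 39 of 47 photosynthesis genes, and raised 14 of 14 genes of ribosome assembly, 16 of 22 of glucosinolate synthesis and 9 of 11 of the response to low oxygen, although none of these lists passed camera with an estimated correlation. ASN1, an asparagine synthetase known to be induced in darkness, fell from 840 ± 46.1 CPM (mean ± SD, n = 3) in mannitol to 0.574 ± 0.532 CPM in fructose. STP1, a hexose importer of the plasma membrane, fell by 6.66 on the log2 scale to 14.7 CPM. The nucleolar methyltransferase gene FIB2 rose from 7.68 to 258 CPM, and the phytoglobin gene PGB1 rose from 1.31 to 229 CPM.

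Of 18784 genes tested, 6869 were higher and 5546 lower in fructose than in mannitol (edgeR, adjusted p under 0.05), and 4166 and 2679 of these changed at least 2-fold. The largest falls were those of ASN1 (-10.49 ± 0.57), SEN5 (-9.99 ± 0.48), the defensin-like PDF1.4 (-9.04 ± 0.20), the xyloglucan-modifying enzyme XTH25 (-8.34 ± 0.24) and GAT1_2.1, a glutamine amidotransferase. For GAT1_2.1, fructose held 3 counts in all and mannitol 2269, a ratio of 914 with a 95% interval of 312 to 4434. Intervals and floors given here cover counting error only. The largest rises included GH3.3, which conjugates auxin to amino acids (9.06 ± 0.90), and the efflux carrier DTX1 (8.21 ± 0.62). AOX1B, an alternative oxidase, had 0 counts in mannitol and 15.2 ± 3.57 CPM in fructose, at least 289-fold higher over a floor of 3 counts over the group. The glycosyltransferase UGT73C1 had 1 count in mannitol and was higher by a ratio of 1329 (238 to 52509), and the low-oxygen transcription factor HRE2 had 2 counts and a ratio of 507 (140.1 to 4191).

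In the sugar starvation list, 20 of 22 genes fell and 1 rose, with a median of -4.17. TPS11 (-4.30 ± 0.10) and TPS8 (-4.31 ± 0.15) belong to the trehalose phosphate synthase family, and MCCA (-4.04 ± 0.12) and IVD (-3.58 ± 0.12) act in leucine breakdown. DIN11 rose by 1.47 ± 0.30 against that direction. The photosynthesis list had 39 of 47 genes lower and 0 higher, 44 lower when adjusted over the list alone, with a median of -1.90. Among them were the Rubisco small subunit RBCS2B (-2.94 ± 0.22), the plastid glyceraldehyde phosphate dehydrogenase GAPA (-2.83 ± 0.39) and the Rieske protein PETC (-1.82 ± 0.21). Both lists stood apart from other genes in camera of limma (adjusted p = 8.19e-11 and 4.60e-07). With an estimated correlation, adjusted p was 0.623 and 0.715.

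All 14 genes of ribosome biogenesis rose (median 2.83), among them FIB2 (5.07 ± 0.20), the snoRNP proteins CBF5 (3.22 ± 0.14) and NOP56 (3.15 ± 0.11) and the assembly factor BRX1-1 (2.99 ± 0.14). Of 22 glucosinolate genes 16 rose and 0 fell (median 1.34), with CYP79B2 (2.33 ± 0.15), the sulfotransferase SOT17 (1.67 ± 0.18), UGT74B1 (1.35 ± 0.10) and SUR1 (1.33 ± 0.13) as examples. In the low-oxygen list 9 of 11 rose and 2 fell (median 2.57): PGB1 (7.42 ± 0.46), the pyruvate decarboxylase PDC1 (6.98 ± 0.50) rose, as did ADH1 (from 23.2 to 122 CPM), while SUS1 (-0.45 ± 0.12) and HRE1 (-1.33 ± 0.31) fell. Clock genes were lower in 16 of 24 cases and higher in 1 (median -0.92), as for RVE4 (-3.11 ± 0.19), LNK2 (-2.84 ± 0.17) and PRR7 (-1.62 ± 0.09), while GRP7 rose by 1.91 ± 0.31. The limma camera test called these 4 lists (adjusted p = 4.28e-07, 0.00504, 0.0444 and 0.000293 in this order). Adjusted p with an estimated correlation was 0.623, 0.715, 0.675 and 0.623.

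Among the sugar genes, ERDL6, a glucose exporter of the vacuole, fell from 174 ± 7.89 to 23.9 ± 1.74 CPM (-2.86 ± 0.11). The tonoplast sugar transporter TST1 fell (-1.27 ± 0.10) while its relative TST2 rose from 29.8 ± 2.73 to 68.4 ± 11.9 CPM. SWEET2 fell (-2.07 ± 0.24) and SWEET17, a fructose carrier of the vacuolar membrane, rose (1.25 ± 0.10). SWEET16 was lower in fructose, where 1 count was left, by a ratio of 155 (27.3 to 6155). FINS1, the cytosolic fructose bisphosphatase named after fructose insensitivity, fell from 86 ± 11.6 to 8.59 ± 1.36 CPM (-3.32 ± 0.20), and the glucose sensor HXK1 rose (1.08 ± 0.14). ANAC089, a transcription factor linked to fructose signalling, held 37.5 ± 4.37 CPM in fructose and 41.8 ± 2.13 CPM in mannitol (-0.16 ± 0.11; edgeR adjusted p = 0.211). TST3 had too few counts to be tested in the discs. The transporter and sugar metabolism lists were mixed: 3 of 14 vacuolar transporters rose and 8 fell, and of 15 plasma membrane transporters 6 rose and 7 fell, with 3 up and 7 down when pairs were merged, including STP14 (-5.99 ± 0.15), STP4 (-2.35 ± 0.11) and the inositol transporter INT4 (-3.09 ± 0.22). Of 21 genes of sucrose and hexose metabolism 10 rose, as the kinase-family gene AT5G51830 did (3.26 ± 0.33), and 8 fell, as the invertase CINV1 did (-2.15 ± 0.08). The median of that list was 0.41 while its mean was 0.01 and its test pointed down. None of these 3 lists passed limma's camera test (adjusted p = 0.0879, 0.119 and 0.901).

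Other lists fixed for this tissue did not pass the camera test, although many of their members did pass the edgeR test. In starch synthesis 9 of 18 rose and 2 fell, with the glucose phosphate importer of plastids GPT2 (5.39 ± 0.42) and the pyrophosphorylase subunit APL2 (2.91 ± 0.10) up and APL1 (-2.14 ± 0.20) down. Starch degradation had 8 of 19 up and 4 down, including SEX4 (2.67 ± 0.38) and the beta-amylase family member BAM9 (-5.14 ± 0.23). In the anthocyanin list 10 of 14 rose and 1 fell, with the chalcone synthase CHS up by 6.03 ± 1.52, from 0.919 to 57.6 CPM, and TTG1 down by 0.87 (-0.87 ± 0.08). The fructose libraries differed here, since the median member stood at 2.89, 0.02 and 2.82 (log2 CPM) above the mannitol mean in replicates 1 to 3, so the rise rested on replicates 1 and 3. Abscisic acid genes rose in 7 of 13 cases, 6 when adjusted over the list alone, and fell in 0, as ABI2 (2.21 ± 0.20) did. Phosphate starvation had 7 of 11 up and 0 down, and the cell cycle list had 6 of 10 up and 1 down, with CYCD2-1 up (1.90 ± 0.12) and CYCD3-2 down (-0.64 ± 0.13). Nitrogen assimilation had 6 of 13 up, 7 over the list alone, and 4 down, where the nitrite reductase NIR1 (2.19 ± 0.14) and the nitrate reductase NIA1 (1.61 ± 0.24) rose and the glutamate dehydrogenase GDH1 (-1.96 ± 0.08) fell. Cell wall expansion was split, with 6 of 14 up and 4 down, although the expansin EXPA10 rose from 0.883 to 158 CPM (7.50 ± 0.22).

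Smaller or mixed counts were found in the remaining lists. Rises and falls numbered 8 and 7 of 17 in trehalose metabolism (8 and 8 adjusted over the list alone), 6 and 4 of 17 in salicylic acid defence, 7 and 7 of 22 in the jasmonate list, 2 and 3 of 12 in the cold list (2 and 2 over the list alone), 3 and 1 of 8 in the heat shock list (3 and 0 over the list alone), 2 and 5 of 11 in senescence and 0 and 3 of 7 in chlorophyll synthesis. Among markers of cell types, 0 rose and 3 of 4 fell for phloem companion cells, with the sucrose carrier SUC2 down (-1.04 ± 0.21). For guard cells 2 of 6 rose, the potassium channels GORK (3.34 ± 0.34) and KAT1 (1.96 ± 0.17), and 0 fell. Epidermis markers had 0 up and 2 of 5 down, with the homeodomain gene ATML1 at -1.42 ± 0.11, and flower markers had 0 up and 1 of 2 down. No seed storage gene had enough counts in either experiment, so 0 were tested. Median, mean and test differed in sign for trehalose metabolism (0.37, -0.06, down), senescence (-0.39, 0.08, down) and guard cells (-0.16, 0.67, up). Scaling by library size only moved the median of all genes by 0.25 and the share of higher calls from 55.3% to 68.2%.

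Glucose against mannitol shows the response to the other hexose under the same handling. Glucose lowered every tested gene of photosynthesis and of chlorophyll synthesis, lowered most sugar starvation and cold-regulated genes, and raised all ribosome biogenesis genes and 9 of 11 low-oxygen genes, while 1 fell. Here too no list passed camera with an estimated correlation. The carbonic anhydrase CA2 fell from 1366 ± 536 to 4.14 ± 0.78 CPM (n = 3 each), and the dark-inducible gene DIN1 fell from 2238 ± 41.4 to 7.75 ± 2.43 CPM. PDC1 rose from 0.217 ± 0.111 to 250 ± 107 CPM, and DTX1 rose from 0.672 ± 0.234 to 1090 ± 437 CPM. Reads from the mitochondrial genome made up 0.0480% to 0.0560% of the counts in glucose, 0.0104% to 0.0148% in mannitol and 0.0136% to 0.0221% in fructose.

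Of the same 18784 genes, 7224 were higher and 6669 lower in glucose (edgeR, adjusted p under 0.05), 4737 and 4023 of them at least 2-fold. ASN1 (-13.00 ± 0.68), PDF1.4 (-8.84 ± 0.20), CA2 (-8.36 ± 0.62) and DIN1 (-8.17 ± 0.33) fell most, with GAT1_2.1, which had 2 counts in glucose and was lower by a ratio of 1238 (342 to 10232). DTX1 (10.64 ± 0.66) and PDC1 (10.17 ± 0.50) were among the largest rises. UGT73C1 was higher by a ratio of 6701 (1202 to 264720) and HRE2 by a ratio of 2680 (741 to 22131), over 1 and 2 counts in mannitol. AOX1B was at least 224-fold higher, again over 0 counts in mannitol.

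The photosynthesis list had 0 of 47 genes higher and 47 lower (median -4.83), among them GAPA (-5.28 ± 0.43), RBCS2B (-5.07 ± 0.24), GAPB (-4.04 ± 0.34) and PETC (-3.65 ± 0.23). All 7 chlorophyll synthesis genes fell (median -2.93), including the glutamyl-tRNA reductase HEMA1 (-2.93 ± 0.26), the chlorophyllide oxygenase CAO (-4.14 ± 0.43) and the magnesium chelatase subunit CHLI1 (-1.95 ± 0.23). Of the 22 sugar starvation genes 19 fell and 2 rose (median -3.53), with MCCA (-4.55 ± 0.12) and TPS8 (-4.62 ± 0.15) down and DIN11 (3.37 ± 0.33) and DIN2 (3.24 ± 0.79) up. In the cold list 9 of 12 fell and 1 rose (median -2.00), with the dehydrin COR47 (-2.39 ± 0.25), COR414-TM1 (-3.06 ± 0.40) and KIN2 (-2.93 ± 0.49) down. All 4 of these lists passed the limma camera test (adjusted p = 8.57e-12, 0.00907, 6.66e-07 and 0.0423). These had adjusted p, with an estimated correlation, of 0.663, 0.663, 0.623 and 0.763.

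Ribosome biogenesis rose in 14 of 14 genes (median 3.45), with FIB2 at 5.92 ± 0.20 and CBF5 at 3.84 ± 0.15. Low-oxygen genes rose in 9 of 11 cases and fell in 1 (median 3.11), with PGB1 (9.03 ± 0.49) and PDC2 (1.55 ± 0.12) up and SUS1 (-0.29 ± 0.12) down. Clock genes fell in 16 of 24 cases and rose in 4, 5 over the list alone (median -1.001), with RVE4 (-3.37 ± 0.19) and LNK2 (-3.06 ± 0.17) down and GRP7 (3.46 ± 0.33) and LUX (1.54 ± 0.21) up. All 3 lists passed the limma camera test (adjusted p = 5.22e-07, 0.0104 and 0.0250). With an estimated correlation, adjusted p was 0.623, 0.632 and 0.623. Among the sugar genes FINS1 (-3.99 ± 0.21), ERDL6 (-1.50 ± 0.11), SWEET2 (-1.61 ± 0.24) and TST1 (-0.97 ± 0.10) fell, and SWEET17 (1.07 ± 0.10), HXK1 (0.77 ± 0.14) and TST2 (0.65 ± 0.18) rose. SWEET16, at 1 count in glucose, was lower by a ratio of 139.7 (24.6 to 5561), and ANAC089 held 41.3 ± 3.33 CPM in glucose (-0.02 ± 0.11).

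The camera test called no other list in glucose. Rises and falls numbered 4 and 9 of 14 for vacuolar transporters, 6 and 7 of 15 for plasma membrane transporters, 8 and 9 of 21 for sucrose and hexose metabolism, 6 and 6 of 18 for starch synthesis and 3 and 7 of 19 for starch degradation (3 and 6 adjusted over the list alone). The invertase VINV2 fell from 879 to 11.4 CPM (-6.26 ± 0.61), STP1 fell by 6.62 on the log2 scale, and AT5G51830 rose to 416 CPM (5.06 ± 0.36). Glucosinolate genes rose in 12 of 22 cases and fell in 3, with CYP79B2 at 3.31 ± 0.16, and the list median stood at 0.07, 0.99 and 1.32 (log2 CPM above the mannitol mean) in glucose replicates 1 to 3, so replicate 1 hardly moved. Nitrogen assimilation had 7 of 13 up and 4 down, and the plastid glutamine synthetase GLN2 fell (-2.21 ± 0.16). The jasmonate list had 8 of 22 up and 12 down, and 2 of 14 anthocyanin genes rose and 1 fell. Among markers of cell types, 4 of 4 fell for phloem companion cells (median -1.11), 3 of 5 for the epidermis (median -1.87) and 1 of 2 for flowers, with 0 up in each, and 2 of 6 rose and 1 fell for guard cells. XTH15 had 0 counts in glucose and 6.24 CPM in mannitol, at least 130-fold lower. Median, mean and test differed in sign for plasma membrane transporters (0.25, -1.02, down), starch synthesis (-0.31, 0.32, down), trehalose metabolism (0.77, -0.26, down), the anthocyanin list (0.50, 1.64, down) and salicylic acid defence (-0.17, 0.07, down). Scaling by library size only moved the median of all genes by 0.20 and the share of higher calls from 52.0% to 60.0%.

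**Figure D3:**
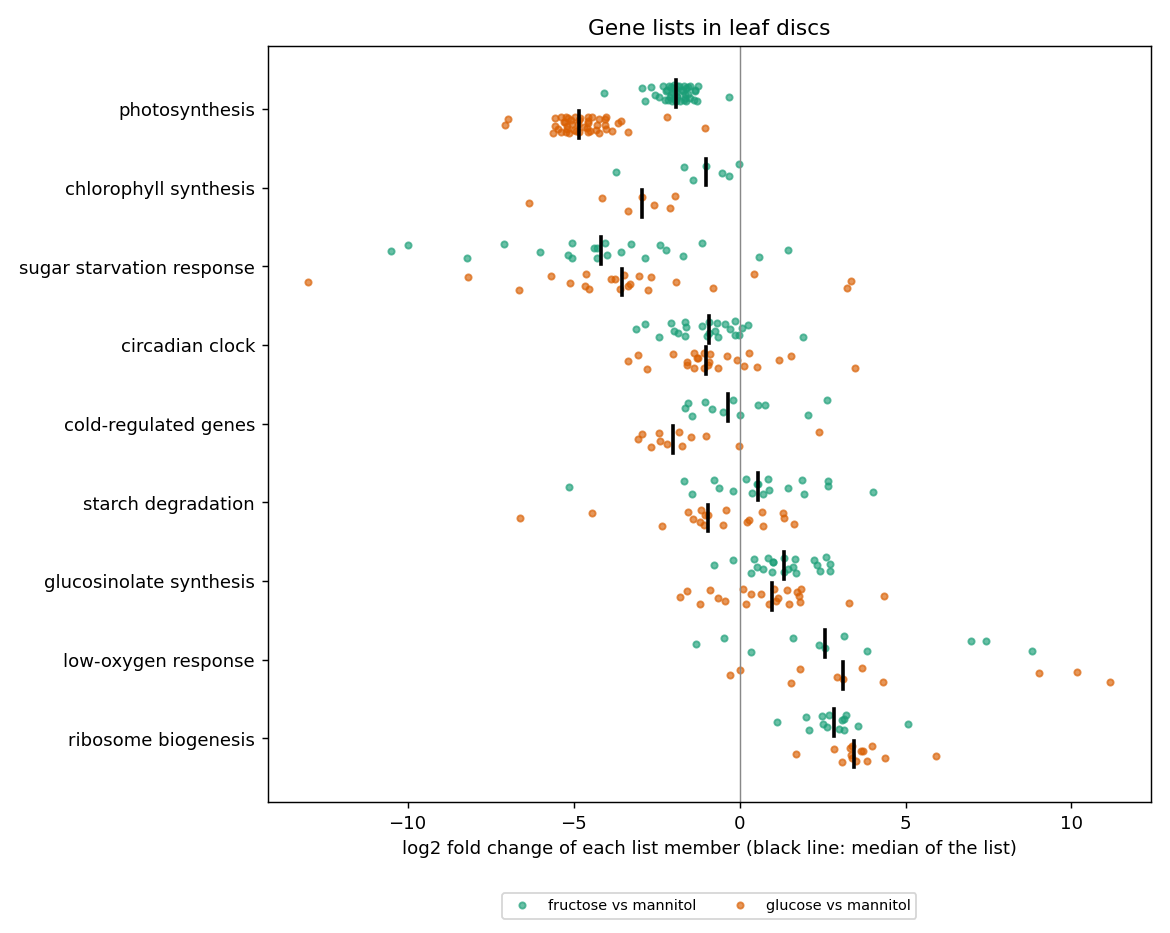
Log2 fold change (horizontal axis) of each tested member of 9 gene lists in leaf discs, for fructose against mannitol and glucose against mannitol (n = 3 per group). Each point is a gene and each black line a list median; the photosynthesis median is -1.90 in fructose and -4.83 in glucose, and that of ribosome biogenesis is 2.83 and 3.45.

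Setting fructose against glucose tests directly where the responses to the 2 hexoses differ. Most photosynthesis, chlorophyll synthesis and starch genes, 7 of 12 cold-regulated genes and 6 of 13 abscisic acid genes were higher in fructose, and all ribosome biogenesis genes and most low-oxygen genes were lower, although none of these lists passed camera with an estimated correlation. The antenna protein gene LHCB2.3 stood at 208 ± 100.03 CPM in fructose and 9.79 ± 12.1 CPM in glucose (n = 3 each; 4.40 ± 0.93), and its relative LHCB1.1 at 2492 ± 580 and 197 ± 222 CPM (3.66 ± 0.78). These antenna genes have near-identical copies, so their separate levels are uncertain. PDC1 was at 27.5 ± 6.24 CPM in fructose and 250 ± 107 CPM in glucose (-3.19 ± 0.31). ERDL6 was also lower in fructose (-1.36 ± 0.11) while ERDL4 was higher (0.62 ± 0.13).

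In all 4646 genes were higher and 4623 lower in fructose than in glucose (edgeR, adjusted p under 0.05), 1975 and 1226 at least 2-fold. The lowest were BRU6, an auxin-conjugating enzyme (-3.99 ± 0.60), the inositol oxygenase MIOX2 (-3.74 ± 0.35), SEN5 (-3.35 ± 0.38), PDC1 and DREB2C (-3.14 ± 0.42). JAL23 (3.77 ± 0.95), MBP1 (3.70 ± 1.02) and BGLU18 (3.60 ± 0.99) were among the highest, but none of the 3 passed the edgeR test without fructose replicate 3 (adjusted p = 0.052, 0.0715 and 0.0686), and over all alternatives their adjusted p ran from 0.000318 to 0.0767. MBP1 and BGLU18 did not pass without glucose replicate 3 either (edgeR adjusted p = 0.0544 and 0.0559).

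The photosynthesis list had 44 of 47 genes higher, 47 when adjusted over the list alone, and 0 lower (median 2.88), with GAPB (2.36 ± 0.32), RBCS2B (2.14 ± 0.21) and PETC (1.84 ± 0.22). Chlorophyll synthesis had 5 of 7 higher (median 2.09), among them the magnesium chelatase subunit CHLH (2.84 ± 0.44) and CAO (2.48 ± 0.40). Starch synthesis had 11 of 18 higher and 1 lower (median 1.16), with APL1 (1.96 ± 0.22) higher and APL2 (-0.42 ± 0.09) lower. Starch degradation had 13 of 19 higher and 0 lower, 16 and 1 over the list alone (median 1.22), with BAM9 (1.46 ± 0.26) and BAM1 (0.94 ± 0.16). In limma's camera test these 4 lists stood apart (adjusted p = 3.52e-15, 0.00316, 0.00210 and 0.000505). Adjusted p with an estimated correlation was 0.632, 0.632, 0.664 and 0.666.

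Cold-regulated genes were higher in 7 of 12 cases and lower in 0 (median 1.56), with COR15A (2.45 ± 0.49) and COR414-TM1 (2.02 ± 0.38). Abscisic acid genes were higher in 6 of 13 cases and lower in 1 (median 1.85), with the phosphatase ABI1 (1.32 ± 0.24) and the bZIP factor ABF3 (1.96 ± 0.45) higher and ABI5 (-1.56 ± 0.23) lower. Glucose replicate 2 stood apart from the other glucose libraries in these lists and in those of starch. Relative to the mannitol mean, the median abscisic acid gene stood at -1.95, 0.41 and -0.95 (log2 CPM) in glucose replicates 1 to 3 and at 1.17, 1.15 and 1.87 in fructose, and the median cold-regulated gene at -2.84, -0.92 and -2.12 in glucose and -0.52, -0.51 and 0.06 in fructose. The photosynthesis medians were -6.12, -3.84 and -5.26 in glucose. Those of starch degradation were -1.24, -0.07 and -1.07 in glucose and 0.57, 0.14 and 0.92 in fructose. Those of starch synthesis were -0.81, 0.35 and -0.50 in glucose and 0.85, 0.42 and 0.96 in fructose. In both starch lists glucose replicate 2 thus lay close to the lowest fructose value. All 14 ribosome biogenesis genes were lower (median -0.76), as PES (-1.08 ± 0.14) and BOP1 (-0.86 ± 0.14) were. Low-oxygen genes were lower in 7 of 11 cases (median -1.21), with PDC2 (-1.21 ± 0.12) and PGB1 (-1.61 ± 0.34). In the sugar starvation list 11 of 22 were lower and 1 higher, 12 and 3 over the list alone (median -0.30), with the proline dehydrogenase PRODH1 (-2.28 ± 0.20) and the raffinose synthase family gene DIN10 (-2.42 ± 0.25) lower. The limma camera test called these 5 lists as well (adjusted p = 0.00408, 0.00945, 1.79e-05, 0.0125 and 0.0239). These had adjusted p, with an estimated correlation, of 0.666, 0.715, 0.632, 0.632 and 0.639.

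For the other sugar genes the differences between the hexoses were small. FINS1 (0.67 ± 0.21) and TST2 (0.55 ± 0.18) were higher and TST1 (-0.31 ± 0.10) lower in fructose, but these calls depended on single libraries. In edgeR the adjusted p of FINS1, TST2 and TST1 was 0.0886, 0.106 and 0.0543 without fructose replicate 3 and 0.0688, 0.0913 and 0.071 without glucose replicate 1. It was 0.0694 for FINS1 and 0.0908 for TST2 without glucose replicate 3 and 0.0726 for TST1 without fructose replicate 2, in a range of 0.00322 to 0.106 over their alternatives in edgeR and other tools. HXK1 (0.31 ± 0.14), SWEET17 (0.18 ± 0.10), SWEET2 (-0.47 ± 0.25) and ANAC089 (-0.14 ± 0.11) did not pass the test (edgeR adjusted p = 0.0934, 0.146, 0.140060 and 0.289), and SWEET16 had 1 count in each sugar. HXK1 passed without glucose replicate 2 (0.49; edgeR adjusted p = 0.00542, with a range of 0.00542 to 0.273 over its alternatives). Epidermis markers were higher in fructose in 2 of 5 cases (median 0.93), phloem markers in 1 of 4 and flower markers in 1 of 2, with 0 lower in each, and guard cell markers had 1 of 6 higher and 2 lower. Where median, mean and camera differed in sign, the values were -0.03, 0.08 and down for plasma membrane transporters and -0.11, 0.48 and down for the jasmonate list.

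The responses to the hexoses overlapped in 5744 higher and 4746 lower genes, where independent lists would share 2642 and 1969. Unchanged groups simulated against the mannitol libraries shared at most 1 called gene in 20 simulations, which says little because such groups call almost no genes. Part of the excess may come from the shared mannitol libraries, which were not split between the hexoses to test this. Across genes, which are not independent replicates, the fold changes had r = 0.889 against a simulated 0.506, and a covariance of 2.55 against a simulated 0.0384, a difference of 2.52. Only 108 genes were called in opposite directions, 52 of them higher in fructose and lower in glucose. Of the 9269 genes called between the hexoses, 5825 (62.8%) had their fructose level between those in mannitol and glucose, 1424 (15.4%) lay beyond glucose and 2020 (21.8%) lay on the other side of mannitol.

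The comparison of the ERDL4 overexpressors with wild type asks what raised ERDL4 expression does to the leaf transcriptome. In both lines most genes of anthocyanin synthesis, the abscisic acid response, the cold response and phosphate starvation rose, and most genes of photosynthesis, chlorophyll synthesis and cell wall expansion fell. Of the cell cycle genes 9 and 6 of 12 fell (5 and 4 with merged pairs), and of the nitrogen assimilation genes 8 and 10 of 14 (7 and 8 with merged pairs). DFR, which encodes a reductase of anthocyanin synthesis, rose from 1.56 ± 2.26 CPM in wild type to 131 ± 66.6 CPM in overexpressor 1 and 457 ± 23.2 CPM in overexpressor 2 (n = 3 each). RD29A, a marker of abscisic acid and cold responses, rose from 241 to 2126.5 and 2489 CPM. EXPA8, an expansin that loosens cell walls, fell from 100.1 ± 37.0 CPM to 1.68 ± 1.94 and 0.438 ± 0.201 CPM.

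Of 18703 genes tested in leaves, 4018 were higher and 4178 lower in overexpressor 1, and 3851 higher and 4016 lower in overexpressor 2 (edgeR, adjusted p under 0.05). At least 2-fold changes were seen in 1440 and 1803 genes and in 1469 and 1712 genes. The mean of both lines differed from wild type in 4447 higher and 4735 lower genes. Replicates 2 and 3 of each line were closer to each other than other replicate pairs were. With each such pair merged into 1 library, 2485 genes were higher and 2625 lower in overexpressor 1 and 2636 and 2670 in overexpressor 2. Scaling by library size only moved the median of all genes by 0.21 and 0.27 and the share of higher calls from 49.0% to 68.7% in overexpressor 1 and from 49.0% to 74.4% in overexpressor 2, and for the mean of the lines from 48.4% to 71.0%.

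The largest rises in overexpressor 1 were those of LEA7 (8.60 ± 1.69), the membrane protein TSPO (7.96 ± 1.03), the sugar carrier SWEET15 (7.56 ± 1.14), the anthocyanin regulator MYB90 (7.30 ± 0.78) and HIPP22, which had 1 count in wild type and a ratio of 728 (130.4 to 28800). In overexpressor 2 they were UF3GT, a glycosyltransferase of anthocyanins (8.67 ± 0.68), DFR (8.21 ± 0.99), LEA7 (7.99 ± 1.72), MYB90 (7.75 ± 0.78) and HIPP22, with a ratio of 344 (61.3 to 13622). LEA7 did not pass in either line with limma-voom (adjusted p = 0.28 and 0.247), against adjusted p from 8.5e-15 to 0.28 over its alternatives. The largest falls in overexpressor 1 were those of BZIP61 (-5.96 ± 0.52), EXPA8 (-5.89 ± 0.66), the ERF factor ESE3 (-5.11 ± 0.48), DIN10 (-4.87 ± 0.53) and XTH6 (-4.75 ± 0.66). In overexpressor 2 they were EXPA8 (-7.80 ± 0.80), DIN10 (-6.44 ± 0.63), the defensin PDF1.2B (-6.43 ± 1.29), the antenna gene LHCB1.4 (-5.96 ± 0.59) and BZIP61, whose 3 counts were lower by a ratio of 331 (113 to 1607). PDF1.2B missed the threshold with limma-voom (adjusted p = 0.0544, the highest over its alternatives, whose lowest was 8.18e-07).

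Anthocyanin and flavonoid genes rose in 16 of 19 cases in overexpressor 1 and fell in 0, with 1 fall when adjusted over the list alone, and rose in 17 and fell in 1 in overexpressor 2 (medians 3.54 and 5.16). The regulators MYB75 (4.70 ± 0.46 in overexpressor 1) and TT8 (6.14 ± 0.68 and 7.33 ± 0.66) and the glucosyltransferase UGT75C1 (3.91 ± 0.41 and 5.64 ± 0.43) rose, and TTG1 fell in overexpressor 2 (-0.72 ± 0.15). All 13 abscisic acid genes rose in both lines (medians 2.64 and 2.56), among them ABF3 (2.18 ± 0.23 and 1.79 ± 0.23), ABI2 (2.53 ± 0.29 in overexpressor 1) and ABI1 (1.57 ± 0.20 and 1.45 ± 0.20). Phosphate starvation genes rose in 12 of 13 cases, 13 over the list alone, and in 13 of 13 (medians 2.29 and 2.04). SQD1 (1.56 ± 0.15 and 1.36 ± 0.14) and SQD2 (2.24 ± 0.20 and 1.79 ± 0.19) make sulfolipids, and MGD3 (3.39 ± 0.31 and 3.13 ± 0.31) makes galactolipids. Cold-regulated genes rose in 9 and 10 of 12 cases (medians 1.85 and 1.99), with COR15A (2.48 ± 0.35 and 2.87 ± 0.35) and COR414-TM1 (1.74 ± 0.23 and 1.67 ± 0.23). The limma camera test called these 4 lists in overexpressor 1 (adjusted p = 6.66e-07, 6.05e-08, 3.45e-07 and 0.000336) and in overexpressor 2 (adjusted p = 1.06e-09, 1.35e-07, 1.59e-06 and 9.79e-06). With an estimated correlation, adjusted p was 0.623, 0.623, 0.632 and 0.663 in overexpressor 1 and 0.623, 0.623, 0.632 and 0.632 in overexpressor 2.

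Libraries that stood apart on the leading component did so in these lists too. Relative to the wild-type mean, the median member of the abscisic acid list stood at -0.34, 0.72 and -0.33 (log2 CPM) in wild-type replicates 1 to 3, against 2.23, 3.05 and 3.00 in overexpressor 1 and 2.75, 2.39 and 2.37 in overexpressor 2. The phosphate list had medians of -0.24, 0.82 and -0.47 in wild type, and the cold list -0.43, 0.67 and -0.20. For photosynthesis the wild-type values were 0.16, -0.34 and 0.17, those of overexpressor 1 were -0.79, -1.21 and -1.14 and those of overexpressor 2 were -1.07, -1.46 and -1.47. Anthocyanin genes had medians of 2.75, 3.69 and 3.80 in overexpressor 1 and 5.48, 5.12 and 5.15 in overexpressor 2.

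Photosynthesis genes fell in 45 of 47 cases in overexpressor 1 and 46 in overexpressor 2, while 1 rose in each (medians -1.05 and -1.32). The photosystem I subunits PSAN (-1.71 ± 0.18 and -2.13 ± 0.19) and PSAD2 (-1.37 ± 0.15 and -1.62 ± 0.15) fell, and the antenna gene LHCB7 rose from 20.2 to 58.3 and 53.4 CPM. All 7 chlorophyll synthesis genes fell in both lines (medians -1.73 and -1.89), with the protochlorophyllide reductases PORA (-5.48 ± 0.57 and -5.13 ± 0.57) and PORB (-2.41 ± 0.24 and -1.99 ± 0.24). Cell wall expansion genes fell in 11 of 14 cases in each line, 12 over the list alone, and rose in 0 (medians -1.80 and -1.33), with EXPA1 (-4.10 ± 0.24 and -3.32 ± 0.23) and XTH4 (-3.30 ± 0.31 and -3.45 ± 0.31). Cell cycle genes fell in 9 and 6 of 12 cases (medians -0.995 and -0.779), with the replication factor MCM2 (-1.42 ± 0.20 and -1.52 ± 0.20) and the D-type cyclin CYCD3-2 (-1.15 ± 0.15 and -0.95 ± 0.15). Nitrogen assimilation genes fell in 8 and 10 of 14 cases, 9 and 11 over the list alone, and rose in 1 (medians -0.72 and -0.80). NIA1 (-1.66 ± 0.15 and -1.37 ± 0.15) fell, while the glutamine synthetase GLN1.3 rose (1.36 ± 0.20 and 1.41 ± 0.20). The limma camera test called these 5 lists in overexpressor 1 (adjusted p = 1.48e-13, 6.17e-05, 4.73e-05, 0.000313 and 0.00409) and in overexpressor 2 (adjusted p = 1.24e-17, 4.92e-05, 2.48e-05, 0.00945 and 0.00137). Adjusted p with an estimated correlation was 0.632 for photosynthesis in overexpressor 1 and for the cell cycle in overexpressor 2, and 0.623 for the others. With merged pairs 5 cell cycle genes fell in overexpressor 1.

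**Figure D4:**
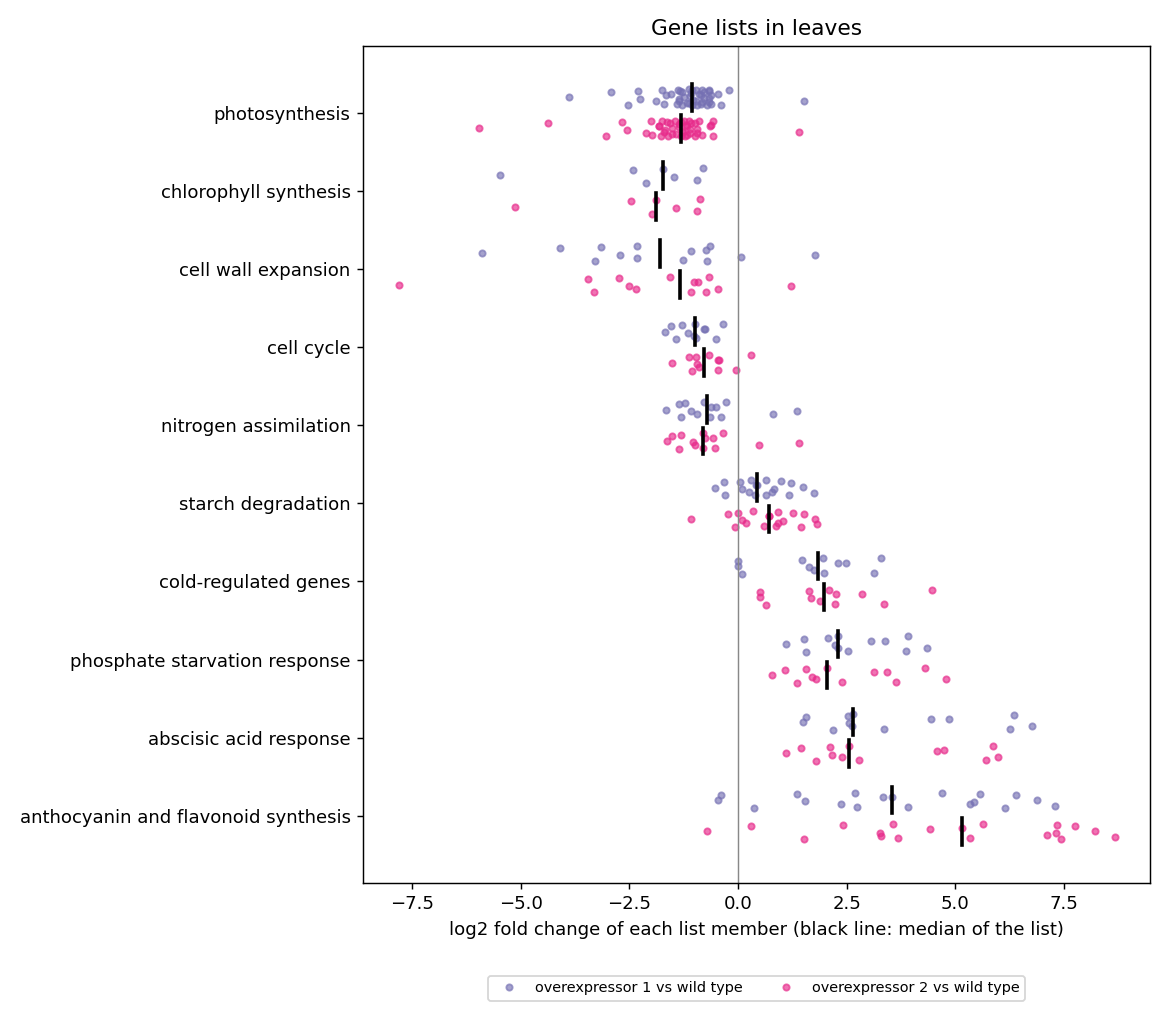
Log2 fold change (horizontal axis) of each tested member of 10 gene lists in leaves, for overexpressor 1 and overexpressor 2 against wild type (n = 3 per group). Each point is a gene and each black line a list median; the anthocyanin medians are 3.54 and 5.16 and the chlorophyll synthesis medians -1.73 and -1.89.

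Genes of starch metabolism rose in part. In starch synthesis 7 of 18 rose in overexpressor 1 and 8 in overexpressor 2, and 2 fell in each (medians 0.21 and 0.25). Granule-bound starch synthase GBSS1 (2.83 ± 0.27 and 3.27 ± 0.28), APL3 (2.33 ± 0.19 and 2.78 ± 0.19) and APL4 (3.45 ± 0.48 and 4.18 ± 0.49) rose, and APL1 fell (-0.52 ± 0.11 and -0.55 ± 0.11). In starch degradation 11 and 13 of 19 rose and 1 fell in each (medians 0.44 and 0.72), with the maltose exporter MEX1 (1.49 ± 0.18 and 1.51 ± 0.18) up. Both lists passed the limma camera test (adjusted p = 0.0448 and 0.00519 in overexpressor 1, 0.0382 and 0.00129 in overexpressor 2). These had adjusted p, with an estimated correlation, of 0.639 and 0.623, and 0.632 and 0.623. With merged pairs, 7 starch degradation genes rose in overexpressor 1.

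Clock genes rose in 12 of 24 cases in each line, 14 and 12 over the list alone, and fell in 1 and 2 (medians 0.35 and 0.47), with LNK1 (0.96 ± 0.13 and 0.83 ± 0.13) and RVE8 (1.37 ± 0.17 and 1.09 ± 0.17) up and CHE (-2.06 ± 0.20 and -2.11 ± 0.20) down. The jasmonate list had 11 and 13 of 23 up, 12 and 14 over the list alone, and 2 down (medians 0.53 and 1.06), with the vegetative storage proteins VSP1 (3.73 ± 0.55 and 5.05 ± 0.57) and VSP2 (4.36 ± 0.61 and 5.06 ± 0.63) up. Glucosinolate genes rose in 11 and 9 of 21 cases, 12 and 9 over the list alone, and fell in 1 (medians 0.38 and 0.32), with CYP79B2 (0.96 ± 0.20 and 1.15 ± 0.20) and MAM3 (0.96 ± 0.18 and 0.90 ± 0.18) up and the regulator MYB51 down in overexpressor 2 (-2.07 ± 0.39). Again in limma's camera test the 3 lists stood apart (adjusted p = 0.00503, 0.0448 and 0.0109 in overexpressor 1, 0.0338, 0.000680 and 0.0423 in overexpressor 2). With an estimated correlation, adjusted p was 0.663, 0.788 and 0.666 in overexpressor 1 and 0.715, 0.666 and 0.715 in overexpressor 2. With merged pairs 4 jasmonate and 4 glucosinolate genes rose in overexpressor 1.

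Camera called 4 lists in a single line, and whether the lines differ in them rests on the comparison of the lines themselves, given with that comparison. Senescence genes rose in 5 of 11 cases and fell in 1 in overexpressor 1, 6 and 1 over the list alone (median 0.91; adjusted p = 0.0408, and 0.682 with an estimated correlation), with the chlorophyll breakdown enzymes PAO (1.24 ± 0.16) and PPH (1.35 ± 0.20) up. In overexpressor 2 it was 4 up and 1 down (0.52; adjusted p = 0.220 in limma's camera test). These medians hung on single libraries, since that of overexpressor 2 was 0.90 without wild-type replicate 2 and that of overexpressor 1 was 0.70 without overexpressor 1 replicate 1. Heat shock genes rose in 4 of 7 cases in each line, 5 and 4 over the list alone (medians 0.69 and 1.15; adjusted p = 0.0529 and 0.0234, the latter 0.623 with an estimated correlation), with HSP70 at 3.35 ± 0.48 and 3.41 ± 0.48. Sugar starvation genes fell in 9 and 11 of 22 cases and rose in 6 and 3, with 10 falls over the list alone in overexpressor 1 (medians -0.46 and -0.84; adjusted p = 0.234 and 0.0213, the latter 0.666 with an estimated correlation). TPS11 (-1.60 ± 0.19 and -2.34 ± 0.20) fell and BCAT2 (2.95 ± 0.41 and 2.88 ± 0.41) rose. Salicylic acid defence genes fell in 3 and 8 of 19 cases and rose in 0 and 1, with 2 falls over the list alone in overexpressor 1 (medians -0.74 and -0.97; adjusted p = 0.067 and 0.0327, the latter 0.788 with an estimated correlation), with EDS1 (-1.37 ± 0.24) down in overexpressor 2. Without overexpressor 1 replicate 1, 12 of the 19 fell in overexpressor 1, and with merged pairs 0 fell in overexpressor 1 and 3 in overexpressor 2.

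Among the sugar genes, SWEET2 (-2.28 ± 0.33 and -2.76 ± 0.35), TST1 (-0.78 ± 0.18 and -0.76 ± 0.18) and FINS1 (-0.74 ± 0.14 and -0.98 ± 0.14) fell in both lines, and TST2 (1.54 ± 0.24 and 1.66 ± 0.24) rose. ANAC089 rose from 13.5 ± 4.22 CPM to 53.6 ± 9.48 and 51.6 ± 5.89 CPM (1.99 ± 0.22 and 1.93 ± 0.22). HXK1 (0.35 ± 0.09 and 0.34 ± 0.09) and SWEET17 (0.50 ± 0.15 and 0.51 ± 0.15) rose as well, but with merged pairs none of these 4 calls passed (edgeR adjusted p = 0.076, 0.0708, 0.119 and 0.0539; their alternatives ranged from 0.000634 to 0.119). In overexpressor 1 the calls of HXK1 and SWEET17 also ended without overexpressor 1 replicate 2 (edgeR adjusted p = 0.0569 and 0.0946), that of SWEET17 without overexpressor 1 replicate 3 (0.0834 in edgeR), and in overexpressor 2 that of SWEET17 without overexpressor 2 replicate 1 (0.065 in edgeR). ERDL6 fell in overexpressor 1 (-0.59 ± 0.21; edgeR adjusted p = 0.0415, with 8 of 20 alternatives past 0.05 and a range of 0.005 to 0.131). In edgeR the call ended without overexpressor 1 replicate 1, 2 or 3 (adjusted p = 0.0968, 0.0635 and 0.0978) and without wild-type replicate 1 or 3 (0.131 and 0.0997). In overexpressor 2 it was at -0.22 ± 0.21 and passed only without overexpressor 2 replicate 1 (-0.52; edgeR adjusted p = 0.0202, with a range of 0.0202 to 0.841). SWEET16 (-0.76 ± 0.30 and -0.41 ± 0.30) and TST3 (0.99 ± 0.49 and 0.66 ± 0.51) did not pass.

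The transporter lists were not called in leaves. Vacuolar transporters had 5 up and 6 down of 15 in overexpressor 1 (6 and 7 over the list alone) and 5 up and 5 down in overexpressor 2, with medians of -0.17 and -0.16 that turned positive with library size only. Plasma membrane transporters had 8 up and 2 down of 16 (8 and 3 over the list alone) and 7 up and 4 down (8 and 5 over the list alone), with the sucrose carriers SWEET12 (2.78 ± 0.36 and 2.93 ± 0.36) and SWEET13 (2.14 ± 0.26 and 2.21 ± 0.26) and SWEET4 (3.40 ± 0.48 and 3.20 ± 0.49) up. Sucrose and hexose metabolism had 11 up and 6 down of 24 (11 and 9 over the list alone) and 10 up and 8 down, with the sucrose phosphate synthase SPSA1 (1.55 ± 0.17 and 1.28 ± 0.17) and HXK2 (1.46 ± 0.14 and 1.58 ± 0.14) up. Trehalose metabolism had 8 up and 8 down of 17 and 6 up and 9 down, with TPS5 up (1.67 ± 0.18 and 1.80 ± 0.18) and TPPB down (-2.67 ± 0.36 and -3.46 ± 0.40). Ribosome biogenesis had 0 up and 5 down of 14 in overexpressor 1 (0 and 3 over the list alone) and 4 up and 0 down in overexpressor 2 (3 and 0 over the list alone). With merged pairs, rises and falls in overexpressor 1 became 7 and 3 in sucrose and hexose metabolism, 3 and 6 in trehalose metabolism and 2 and 8 in sugar starvation. With merged pairs 2 ribosome biogenesis genes fell in overexpressor 1, as 2 did without overexpressor 1 replicate 1, and 0 changed in overexpressor 2 in edgeR. Library size only gave 12 up in overexpressor 2 and turned the median of overexpressor 1 from -0.16 to 0.05. Low-oxygen genes had 2 up and 2 down of 9 (2 and 3 over the list alone) and 1 up and 3 down. Markers of phloem companion cells had 2 and 1 of 4 up (2 and 0 over the list alone), guard cell markers 2 up and 1 down of 6 and 1 up and 1 down, epidermis markers 1 up and 1 down of 5 and 0 up and 2 down, and flower markers 1 and 0 of 2 up. Median, mean and test differed in sign for sucrose and hexose metabolism in overexpressor 2 (0.16, -0.08, up), low-oxygen genes (0.30, -0.07, up and 0.25, -0.39, down), epidermis markers in overexpressor 1 (0.22, 0.12, down) and guard cell markers in overexpressor 2 (-0.05, 0.04, down).

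The lines shared 3037 higher and 3190 lower genes, where independent lists would share 827 and 897, and 7 genes were called in opposite directions. The shared counts were 5243 higher and 1921 lower with library size only and 1902 and 1924 with merged pairs. Unchanged groups simulated against the wild-type libraries shared 0 called genes in edgeR, which says little for the same reason. Part of the excess may come from the shared wild-type libraries, which were not split between the lines to test this. Across genes, which are not independent replicates, the fold changes of the lines had r = 0.934 against a simulated 0.504, and a covariance of 1.02 against a simulated 0.0378, a difference of 0.982.

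Overexpressor 2 held more ERDL4 transcript than overexpressor 1, and comparing the lines asks whether other genes differ with it. ERDL4 was at 584 ± 18.7 and 355 ± 4.55 CPM (n = 3 each), a difference of 0.72 ± 0.13 that edgeR did not call at adjusted p = 0.0782. Library size only, DESeq2, a fit of the 2 groups alone, a fit of all 18 libraries and a fit without wild-type replicate 2 did call it. Only 6 genes were higher and 4 lower in overexpressor 2 (edgeR, adjusted p under 0.05), with 2738 genes at an unadjusted p under 0.05. The cytokinin response regulators ARR6 (2.16 ± 0.29) and ARR7 and the flavonol synthase FLS1 (2.00 ± 0.26) were among the 6, named after their values were seen. On the same libraries DESeq2 called 413 higher and 311 lower genes and limma-voom 3 higher and 4 lower, while edgeR with merged pairs called 0. Leaving out wild-type replicate 2 gave 342 higher and 150 lower genes and leaving out overexpressor 2 replicate 1 gave 81 and 90, whereas leaving out others gave 0 to 19 higher and 0 to 11 lower in edgeR. In the anthocyanin list 14 of 19 genes were higher when adjusted over the list alone, against 1 over all genes (median 1.68), and in ribosome biogenesis 12 of 14 against 0 (median 0.49). In limma's camera these lists, the jasmonate (median 0.64), cold (0.34) and cell cycle (0.25) lists stood higher and photosynthesis (-0.28), sugar starvation (-0.32), phosphate starvation (-0.43), senescence (-0.41), phloem (-0.28) and epidermis (-0.35) lists lower, with adjusted p from 1.96e-09 to 0.0447. Adjusted p with an estimated correlation was 0.623 to 0.769. Several of these differences rested on single libraries. Cold medians stood at 1.48, 2.11 and 2.09 (log2 CPM relative to the wild-type mean) in replicates 1 to 3 of overexpressor 1 and at 2.12, 2.05 and 2.05 in overexpressor 2, and without overexpressor 1 replicate 1 the list differences became 0.11 for cold, -0.21 for sugar starvation and -0.19 for photosynthesis. Jasmonate medians were 0.32, 0.67 and 0.68 in overexpressor 1 and 1.79, 0.84 and 0.71 in overexpressor 2, where replicate 1 stood apart. It did so for phosphate starvation too, with medians of 2.74, 1.79 and 1.61 in overexpressor 2 against 2.39, 2.49 and 2.51 in overexpressor 1, so the lower value rested on the near-identical replicates 2 and 3. Epidermis medians were -0.15, 0.36 and 0.45 in overexpressor 1 and -0.09, -0.21 and -0.21 in overexpressor 2, so overexpressor 1 replicate 1 lay among the overexpressor 2 values.

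The last comparison asks whether genes that respond to fructose in discs changed the same way in the overexpressor leaves. The counts differed with direction, fold and line. Fisher's exact test takes genes as independent, which they are not, so its p-values here do not measure the spread between libraries. The expectation also takes every gene as equally likely to be called, whatever its level. An excess or deficit in 1 direction alone therefore does not show that the directions were shared or opposed. Of 17848 genes tested in both experiments, 1171 were lower in fructose than in mannitol and lower in both lines (expected 921; odds ratio 1.56; Fisher's exact test, adjusted p = 8.32e-26). Another 974 were higher in all 3, below the 1040 expected from independent lists (odds ratio 0.887; Fisher's exact test, adjusted p = 0.00688). The balance depended on the setting, with 2116 higher and 655 lower in all 3 with library size only, and 541 and 710 with merged pairs. With changes of at least 2-fold the overlaps were 389 lower (expected 165; odds ratio 3.39) and 306 higher (expected 214; odds ratio 1.67). Genes raised by fructose and lowered in both lines numbered 1006 (expected 1110) and the reverse 873 (expected 862). Taken singly, the overlaps of the lines lay on opposite sides of the expectation, except for genes lowered in both settings. Whether the lines differ in this was not tested, and the direct comparison of the lines called only 10 genes. In overexpressor 1 the genes raised by fructose overlapped less with higher genes (1131, expected 1384; odds ratio 0.686) than with lower ones (1631, expected 1453; odds ratio 1.28), and the genes lowered by fructose more with higher genes (1348, expected 1147; odds ratio 1.36) than with lower ones (1288, expected 1205; odds ratio 1.13). In overexpressor 2 the raised genes overlapped more with higher genes (1416, expected 1320; odds ratio 1.15) than with lower ones (1174, expected 1399; odds ratio 0.718), and the lowered genes less with higher genes (990, expected 1094; odds ratio 0.840) than with lower ones (1523, expected 1159; odds ratio 1.72).

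The 10 genes with the strongest shared change under the rule for named genes included 4 anthocyanin genes. DFR, LDOX, UF3GT and GSTF12, which carries anthocyanins to the vacuole, rose in both lines (DFR 6.41 ± 0.93 and 8.21 ± 0.99, LDOX 5.56 ± 0.68 and 7.43 ± 0.73, GSTF12 5.43 ± 0.67 and 7.11 ± 0.70). In the discs they had 0 to 2 counts in mannitol. Their ratios in fructose were 506 (90.4 to 20009) for DFR, 334 (59.5 to 13209) for LDOX, 83.2 (22.7 to 692) for UF3GT and at least 76.9-fold for GSTF12. Each of these 4 disc calls was lost without mannitol replicate 3 (edgeR adjusted p = 0.0684, 0.0762, 0.0777 and 0.0807), and over all alternatives their adjusted p ran from 0.00122 to 0.221. In edgeR those of LDOX, UF3GT and GSTF12 were also lost without mannitol replicate 1 (adjusted p = 0.0652, 0.0666 and 0.0678), mannitol replicate 2 (0.0814, 0.0712 and 0.070013) or fructose replicate 1 (0.0582, 0.0572 and 0.0782), and those of UF3GT and GSTF12 without fructose replicate 3 (0.0532 and 0.092028). GASA3, of a gibberellin-regulated family, rose by 5.98 ± 0.97 in fructose and had 1 count in wild type, with ratios of 361 (64.4 to 14279) and 256 (45.6 to 10165). LEA7 (5.41 ± 1.45 in fructose) and AT4G33905 (4.87 ± 0.44, 5.98 ± 0.67 and 5.82 ± 0.68) rose, as did AT4G08570 (8.36 ± 0.94 and 8.77 ± 0.95 in the lines; ratio 227, 77.5 to 1105 in fructose, over 3 counts). DIN10 (-6.02 ± 0.29, -4.87 ± 0.53 and -6.44 ± 0.63) and AT5G44020 (-6.15 ± 0.25, -6.26 ± 0.48 and -6.24 ± 0.49) fell.

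In counts of called genes some lists went the same way in fructose discs and in the lines and others did not, and the difference between the experiments was not tested. Photosynthesis had 39 of 47 genes down in fructose and 45 and 46 in the lines, whereas ribosome biogenesis rose in 14 of 14 genes in fructose with 0 and 4 of 14 up in the lines. Of 24 clock genes 16 fell in fructose, and 12 rose and 1 and 2 fell in the lines (8 and 9 up with merged pairs). Glucose gave a like overlap in the same directions, with 1459 genes lower in glucose and in both lines (expected 1118, odds ratio 1.75) and 908 higher (expected 1073). The genes lowered by glucose also overlapped in excess with genes higher in both lines (1153, expected 1047, odds ratio 1.21), where fructose gave 873 (expected 862). Genes raised by glucose and lower in both lines numbered 951 (expected 1146). The overlaps of glucose with the lines taken singly were 1085 higher genes in overexpressor 1 (expected 1428) and 1365 in overexpressor 2 (expected 1362). This difference was not tested either. Genes called in fructose and not in glucose overlapped in 239 higher (expected 170; odds ratio 1.57) and 97 lower genes (expected 121; odds ratio 0.759), but those raised by fructose overlapped in excess with genes lower in both lines too (229, expected 182; odds ratio 1.36). Genes higher in fructose than in glucose overlapped most with genes lower in both lines, at 1249 (expected 793; odds ratio 2.33), and in excess with genes higher in both lines as well, at 920 (expected 743; odds ratio 1.44). Across genes the fold changes of fructose against mannitol had r = 0.0627 with overexpressor 1 and 0.171 with overexpressor 2 (Spearman's rho -0.0517 and 0.102). As sets, the genes called in a disc comparison stood apart in neither line nor their mean in camera (18 tests, lowest adjusted p 0.159). These sets held 4237 to 6659 genes, and a correlation of 0.01 over so many genes leaves camera little power. The test therefore cannot decide whether the sets moved in the lines.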

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

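The tests of a library deposited as 2, of wild-type replicates along the genotype difference and of transgene level were chosen after the result was seen, as were merging pairs and the share of higher calls without a scale correction. A difference between the overexpressor lines was found in 10 genes by the edgeR test of the lines against each other, which is what singled them out. The groups hold 3 libraries, too few for a test of single libraries. Higher in overexpressor 2 were the cytokinin response regulators ARR6 (2.16; 13.8, 1.44 and 6.44 CPM in wild type, overexpressor 1 and overexpressor 2) and ARR7 (1.69; 17.43, 4.48 and 14.5 CPM), the flavonol synthase FLS1 (2.00; 3.99, 2.89 and 11.5 CPM), AT3G29644 (1.4996; 3.82, 1.36 and 3.85 CPM), AT4G13577 (1.18; 18.4, 6.66 and 15.1 CPM) and AT5G57120 (0.62; 26.6, 21.0 and 32.4 CPM). Lower were the NAD kinase NADK2 (-0.76; 119.7, 118.7 and 70.2 CPM), the boron channel NIP6;1 (-0.87; 33.1, 29.9 and 16.4 CPM), AT5G35970 (-0.90; 551, 665 and 356 CPM) and AT3G06355 (-2.69; 8.38, 20.9 and 3.22 CPM). With merged pairs edgeR called 0 of the 10 (adjusted p from 0.35 to 0.752). Of the 10 splits of these 6 libraries the real one called 10 genes and the highest other 2, and 10 splits are too few for a share under 0.05.

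The number of genes called against wild type was weighed against technical explanations. Summing each near-identical pair of replicates 2 and 3 into 1 library gave 5110 calls in overexpressor 1 instead of 8196, so a spread understated by these pairs may account for part of the count, though merging also lowers the number of libraries. Whether a single library was deposited as 2 in each line stays open. The chi-square per degree of freedom of the pairs was 2.06 in overexpressor 1 and 1.70 in overexpressor 2. Resampled reads would give a value near 1 only if each count were an independent read. The tool that made the counts is not given, so this test cannot decide. A few genes taking most of the counts would move all other genes the same way. With library size only, which leaves such a shift in place, 68.7% of the calls in overexpressor 1 were higher and the others lower. This argues against such a shift as the whole cause, but under another scaling than that of the reported calls. Without the 100 most abundant genes, scaled with TMM, 3993 genes were higher and 4089 lower in overexpressor 1. Of the reported calls 98.0% were kept, which argues against those 100 genes as their cause. Splits called 8196 genes against a highest other of 4 in overexpressor 1 and 7867 against 0 in overexpressor 2, and 10 splits are too few for a share under 0.05. For the mean of both lines, fitted as 3 against 6 libraries, the real split called 8628 and the highest other 94, with 1 of 84 splits as large. This would argue against a random grouping if all libraries were independent. The near-identical replicates 2 and 3 of each line may not be, so the share is uncertain.

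Wild-type replicate 2 lay along the difference between the genotypes, with r across genes of 0.439 and 0.443 between its difference from another wild-type library and the change in overexpressor 2 measured against the remaining library. Variation between plants or pots that the genotype does not set may therefore run along the same genes, and it stays open how much of the difference it carries. Overexpressor 1 replicate 1 differed from replicates 2 and 3 along the same axis (r = -0.595 and -0.588). Across the 9182 genes called in the mean of both lines, the median ratio of the change in overexpressor 2 to that in overexpressor 1 was 0.986 (quartiles 0.775 and 1.249). That of ERDL4 was 1.49, so the measured changes as a whole were not in proportion to the transcript level of the transgene. Both changes share the wild-type libraries, and a difference that the genotype does not set would pull the ratio toward 1. A response in proportion to the transgene therefore stays open. In the anthocyanin list the medians were 3.54 and 5.16, and a response that levels off was not tested.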

How the results depend on the processing

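Merged pairs and leaving out the 100 most abundant genes were chosen after the data were seen. Of 715 named genes by comparison, 639 kept their call in every alternative that keeps the threshold, 76 changed it in at least 1 and 0 reversed. These 715 leave out ERDL4 in the leaf comparisons, whose call between the lines changed in several alternatives. Among all genes, no called gene was called in the opposite direction in any alternative. Genes that changed sign and lost their call were not counted. The fit of only the 2 groups compared was not run for the mean of both lines. Wherever a value below differs from the one reported, the cause was not tested, except that a stricter threshold calls fewer genes by construction. Leaving out a library called more genes in some fits and fewer in others. The lowest library total, 17318810 counts, limits what can be said of genes with few counts.

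Higher and lower counts with an absolute log2 fold change of at least 1 were 4166 and 2679 (fructose vs mannitol), 4737 and 4023 (glucose vs mannitol), 1975 and 1226 (fructose vs glucose), 1440 and 1803 (overexpressor 1 vs wild type), 1469 and 1712 (overexpressor 2 vs wild type), 1475 and 1790 (mean of both overexpressors vs wild type), 306 and 389 (fructose response in the overexpressors), 3467 and 2311 (fructose and glucose response shared) and 1166 and 1297 (overexpressor lines shared), with 1 lower in overexpressor 2 vs overexpressor 1. At an adjusted p under 0.01 in edgeR they were 2654 and 2809 (fructose vs glucose), 2455 and 2598 (overexpressor 1 vs wild type), 2236 and 2364 (overexpressor 2 vs wild type), 438 and 666 (fructose response in the overexpressors), 1736 and 1831 (overexpressor lines shared), 0 and 1 (overexpressor 2 vs overexpressor 1), with 2888 higher for the mean of both overexpressors vs wild type.

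With library size only, 6128 genes were higher in overexpressor 1 vs wild type, and higher and lower counts were 6895 and 2372 (overexpressor 2 vs wild type), 7418 and 3033 (mean of both overexpressors vs wild type), 11 and 2 (overexpressor 2 vs overexpressor 1), 2116 and 655 (fructose response in the overexpressors) and 5243 and 1921 (overexpressor lines shared). With merged pairs they were 2485 and 2625 (overexpressor 1 vs wild type), 541 and 710 (fructose response in the overexpressors) and 1902 and 1924 (overexpressor lines shared), 2670 lower in overexpressor 2 vs wild type, and 0 and 0 for overexpressor 2 vs overexpressor 1 in edgeR. The fructose response in the overexpressors held 239 higher and 97 lower genes not called in glucose vs mannitol. Genes lower in fructose than in glucose and lower in both lines, a different list, numbered 571.

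For overexpressor 2 vs overexpressor 1, higher and lower counts were 413 and 311 with the DESeq2 Wald test, 14 and 11 with no filter, 0 and 1 with the replicate block, 73 and 18 with only the 2 groups compared, and 73 and 91 with all 18 libraries in one fit. Limma-voom and the fit without the 100 most abundant genes each gave 3 higher and 4 lower. Leaving out 1 library gave 0 to 342 higher and 0 to 150 lower. The ERDL4 change between the lines passed the test with library size only (0.78), the DESeq2 Wald test (0.72), only the 2 groups compared (0.72) and all 18 libraries in one fit (0.68), and ran from 0.69 to 0.74 over fits that leave out 1 library. Camera with an estimated correlation called 0 gene lists in leaf discs and 0 in leaves (11 of 196 at an unadjusted p under 0.05), against 22 and 59 reported. Fry called 53 in leaf discs and 64 in leaves, but it tests a list against no change rather than against other genes, so its counts are not comparable with those of camera.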

Other observations

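The library size test by the ratio of spreads was chosen after the result was seen, in place of a slope that a correlation below 1 keeps low, as was the look at genes called in opposite directions. Among the 108 genes called in opposite directions against mannitol, the fructose and glucose changes were 1.29 and -1.50 for CPUORF47, -1.07 and 1.05 for SCPL7, -1.16 and 0.88 for EXL2 and -0.93 and 1.53 for VIM2.

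The response to fructose was smaller than that to glucose, with an SD of the fold changes across genes, which are not independent replicates, that was 0.7979 times that of glucose. The slope was 0.709 for fructose on glucose and 1.11 for glucose on fructose, and neither alone gives the ratio of the responses. A difference in library size is argued against, since the ratio of SDs was 0.7978 after thinning to equal totals. Whether a few abundant genes matter was not tested, because a shift shared by all genes leaves these ratios unchanged. A hypothesis that fructose acts as a weaker form of the glucose treatment would place fructose between mannitol and glucose, and 62.8% of the 9269 genes called between the hexoses lay there while 1424 (15.4%) lay beyond glucose, which argues against it as the whole cause. The 21.8% on the other side of mannitol were counted by sign alone, and values close to mannitol may fall there through noise. Splits called 12415 genes for fructose, 13893 for glucose and 9269 between the hexoses, with a highest other of 0 each in edgeR, and the 10 splits of each are too few for a share under 0.05 (1 split as large, the real one).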
